A study of Drosophila melanogaster with 4 samples.

How the data were processed

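The study profiled where the zinc-finger insulator protein Su(Hw) sat on chromatin in whole white prepupae of Drosophila melanogaster by chromatin immunoprecipitation and sequencing (ChIP-seq). The labels list 4 libraries, 2 from chromatin immunoprecipitated with an affinity-purified rabbit antibody raised against Su(Hw) and 2 from input DNA. All came from one strain, described by its y, cn, bw and sp markers. The labels number the libraries of each group as replicates 1 and 2 and do not say whether these came from separate collections of animals.

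The data analysed here are 1 list of 5357 peaks for the whole series. The score of each peak is the authors' own value, deposited with 2 decimals and written by MACS, per the file headers and columns. The submitters' processing notes name CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2, and the genome build BDGP5; the file header gives FlyBase release 5. The MACS version, its threshold, the use of the input libraries as control and the pooling of the ChIP libraries are not given in the sources used here. The scale of the score (a p-value or q-value, and any multiplier) is not given either, so scores served only to describe and rank peaks within this list. The list holds no values per library. Sequencing depth is therefore unknown, no spread between replicates could be computed, and every interval or p-value below describes peaks or genome windows, which are not biological replicates. No column of per-sample values was present, so 0 such columns were set aside.

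Peaks were assigned by their centres, and coordinates are 1-based on FlyBase release 5. Arm lengths of that release were not used here, so each arm was taken to run from position 1 to the end of its last peak. The following comparisons were fixed before the data were examined; some of their alternatives were added later. The first compared each of the 6 arms (2L, 2R, 3L, 3R, 4 and X) with the other arms. It used an exact two-sided binomial test against the share of summed length, and a two-sided permutation test with 100000 resamples on peaks per complete 500 kb window, both with Benjamini-Hochberg adjustment over the 6 arms. The window test allows for local clustering, which the binomial test ignores, and calls were made on it at an adjusted p of 0.05. The second compared windows of X with windows of the 4 large autosomal arms by the same permutation test, with a 95% percentile interval of the ratio from 10000 resamples of windows. The third set the share of peaks with another peak centre within 10 kb against 10000 uniform placements of the same number of centres per arm. With 100000 permutations the smallest possible p is 1e-05, and with 10000 placements the smallest two-sided p is 0.0002. Such p-values are called permutation p throughout, since the positions or labels were redrawn at random.

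Several comparisons were added after seeing the data. Peaks were divided into weak and strong at a score of 44.7, the middle of the least filled bin between the 2 modes of the score histogram (bins of 0.1 on the log10 scale). The share of weak peaks with an edge within 1 kb of a strong peak was set against 10000 placements of the weak peaks, with their widths, outside the strong peaks of the same arm. Peaks with at most 1 kb between their edges were joined into loci, and loci were placed at random with their widths and at least 1 kb apart. Peak density in the 1 Mb at the centromere-facing (proximal) and the telomere-facing (distal) end of the 5 large arms was compared with the rest of each arm by permuting 500 kb windows within arms. Median widths and scores, of peaks on and off the arms and of strong peaks with and without a weak neighbour (the latter also within 20 classes of score), were compared by permutation tests with 100000 resamples. Repeats of the comparison on and off the arms, for peaks above the median score and for joined loci, used 10000 resamples. Wilson 95% intervals accompany shares and exact Poisson 95% intervals accompany densities. Both cover counting error only and treat peaks as independent.

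The named regions follow a rule fixed before the data were examined: the 15 peaks with the highest scores, the 3 windows of 100 kb with the most peaks and the 3 longest stretches without a peak on the 5 large arms. The planned comparisons with gene structures, distances to transcription start sites, 27 gene lists and the Su(Hw) consensus motif need a genome or annotation of release 5, which was not used here. The gene table at hand is on a later assembly, so no peak was assigned to a gene. Alternatives fixed beforehand covered the peaks above the median score, 100 kb and 1 Mb windows, distances of 2 and 50 kb, and peaks with centres within 1 kb counted once. The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

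The X against autosome window test and the clustering test were tested on simulated points placed on the real arms. There were 5140 points per draw, and more where X was made denser. In 20 draws of uniform points, each of these 2 tests called 0 of 20. Each arm kept its observed number of points, so the X ratio was held near the observed 1.03. For the X test, 0 of 20 therefore says nothing about its rate of false calls. The clustering test called 20 of 20 draws in which 20% of the points had been moved next to another point. The simulated points had no width, unlike the peaks, so neither set of draws shows how the clustering test behaves on peaks with widths. The X test called 20 of 20 draws in which X carried 1.5 times as many points. The comparisons of single arms were not simulated; their window test uses the same permutation code as the X test.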

Results

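Su(Hw) is a zinc-finger DNA-binding protein best known for binding the insulator of the gypsy retrotransposon. Its chromatin occupancy was profiled in white prepupae, the short stage at the onset of metamorphosis when the larva becomes immobile and its cuticle turns into the puparium. The series held 2 Su(Hw) ChIP libraries and 2 input DNA libraries of one strain. The data analysed here were 1 list of Su(Hw) peaks for the whole series, each with a position and the peak caller's score, and no values per library. The depth behind each peak is unknown, and agreement between the replicates could not be assessed.

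Su(Hw) was detected at 5357 peaks, of which 5140 (95.9%) lay on the 6 assembled chromosome arms. The peaks covered 12242 kb in total. Their median width was 1891 bp (interquartile range 572 to 3418 bp), with extremes of 201 and 39336 bp. Scores ran from 5.95 to 1268.69 with a median of 151.91. Wider peaks had higher scores, with a Spearman rho of 0.912 across peaks, which are not independent replicates. The smallest width, 201 bp, was shared by 48 peaks.

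The 15 highest-scoring peaks were found on all 5 large arms and not on chromosome 4. Arm 3L held 5 of them, 3R held 4, 2L held 3, X held 2 and 2R held 1. The strongest lay at 3L:22884862-22892306, was 7445 bp wide and scored 1268.69. It was followed by 2R:3113144-3122908, with a score of 1217.58, and 3R:3708535-3712871, with a score of 1128.93. The next were 3L:22446351-22451849 (score 1112.21), 3L:20174201-20178781 (score 1083.08) and 3R:26307361-26313908 (score 1062.1). On X, the peaks at 1207433-1212561 and 14057132-14060094 scored 1016.39 and 1001.93. The 3 on 2L were at 3128759-3138171, 11471683-11477069 and 2852856-2856532, with scores of 1045.74, 1010.7 and 1006.64. The remaining 4 were 3L:962404-972175 (score 1053), 3R:27281751-27286528 (score 1043.17), 3R:23124882-23130135 (score 1004.55) and 3L:4838913-4843334 (score 979.67). The gene content of these regions was not analysed here.

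The first question was whether Su(Hw) occupancy differed between chromosomes. The dot chromosome 4, a short and largely heterochromatic chromosome, carried 9 peaks, or 7.71 per Mb (95% Poisson interval 3.53 to 14.6), against 43.5 per Mb over the other arms. Its share of the peaks was 0.175% and its share of the summed length 0.98% (exact binomial test, adjusted p = 1.03e-11). In complete 500 kb windows, chromosome 4 held 3 ± 1.41 peaks (SD, 2 windows) and the other arms 21.8 ± 7.84 (SD, 233 windows), with an adjusted permutation p of 0.0138. The strongest of the 9 peaks, at 4:434533-437162, scored 867.59, and the median score of the 9 was 187.22. With 1 Mb windows chromosome 4 has a single complete window, and the adjusted p was 0.159. Both of its 500 kb windows lie in the 1 Mb at its centromere-facing end. The same part of the large arms held 7 ± 6.82 peaks per window (SD, 10 windows). A difference between chromosomes therefore cannot be told apart here from the scarcity of peaks near centromeres described below.

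The 5 large arms were close to one another in peak density. It was 43.8 per Mb on 2L (967 peaks), 42.6 on 2R (900 peaks), 40.2 on 3L (983 peaks), 46.0 on 3R (1282 peaks) and 44.6 on X (999 peaks). The binomial test gave an adjusted p of 0.0234 both for the lower density of 3L and for the higher density of 3R. Neither passed the window test, which takes in the spread between windows: 3L windows held 20.4 ± 7.77 peaks (SD, 48 windows; adjusted permutation p = 0.456) and 3R windows 23 ± 8 peaks (SD, 55 windows; adjusted permutation p = 0.456).

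The X chromosome did not differ past the threshold from the large autosomal arms. X windows held 22.3 ± 7.03 peaks (SD, 44 windows) and autosomal windows 21.7 ± 8.03 (SD, 189 windows). The ratio of X to autosomes was 1.03 with a 95% interval of 0.922 to 1.14 (two-sided permutation p = 0.63). Differences beyond these bounds lay outside the interval over windows, and equal density is not shown.

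**Figure D1:**
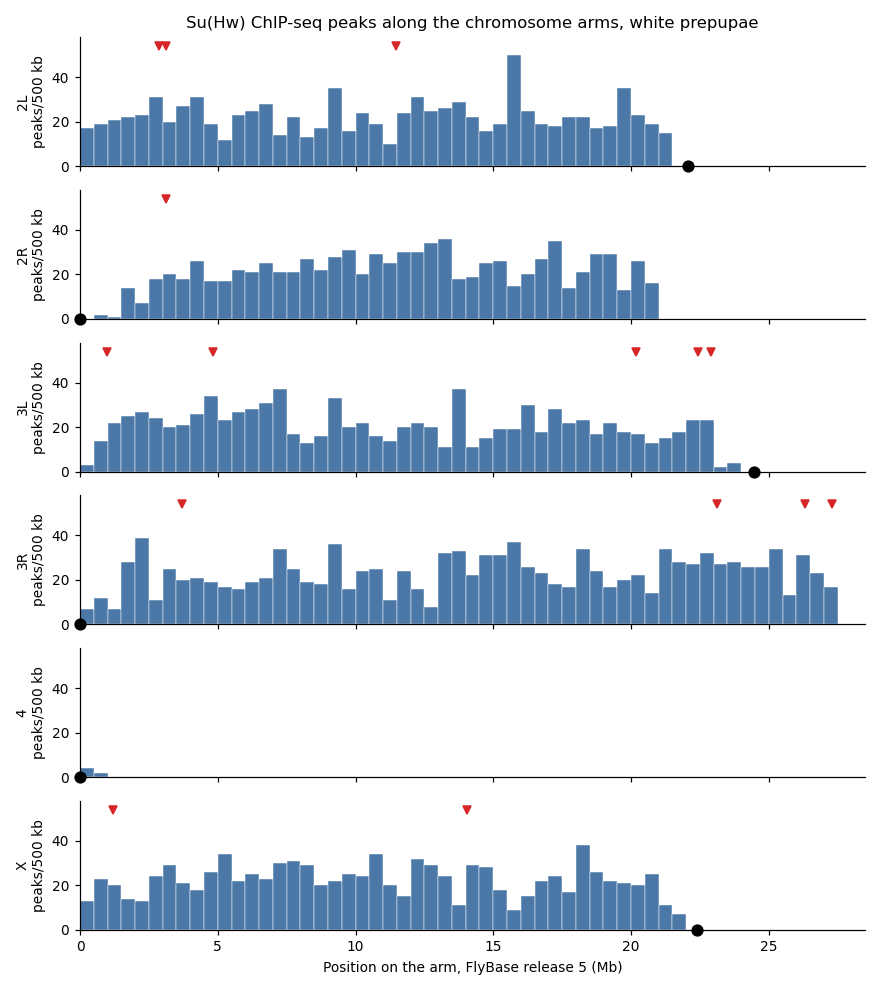
Number of Su(Hw) peaks per 500 kb window (y axis) against position in Mb on FlyBase release 5 (x axis) for the 6 chromosome arms; red triangles mark the 15 highest-scoring peaks and black dots the centromere-facing end of each arm as delimited by the peaks. On the 5 large arms counts fall towards the dots, with 7 ± 6.82 peaks per window in their proximal 1 Mb (SD, 10 windows). Chromosome 4 holds 9 peaks in all.

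Peaks thinned out towards the centromeres. In the proximal 1 Mb of the 5 large arms, 500 kb windows held 7 ± 6.82 peaks (SD, 10 windows), against 22.5 ± 7.29 in the other windows (SD, 223 windows), a ratio of 0.311 (two-sided permutation p = 1e-05, the smallest 100000 permutations can give). The density was lower in 5 of 5 arms. With the proximal 2 Mb the ratio was 0.492 (permutation p = 1e-05). The proximal 1 Mb held 2 peaks on 2R, 7 on 3L, 19 on 2L, 19 on 3R and 23 on X, and the ratio to the rest of the arm ranged from 0.0448 on 2R to 0.498 on X. On 2L, 3L and X the proximal end was set by the last peak, so any empty sequence beyond it is not counted. This comparison was chosen after the data were seen.

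The distal ends showed no difference past the threshold. Their 500 kb windows held 17 ± 6.16 peaks (SD, 10 windows) against 22.1 ± 8.23 elsewhere (SD, 223 windows), a ratio of 0.768 (permutation p = 0.0539, close to the threshold). The windows elsewhere included the sparse proximal ends, which lower their mean. The ratio was below 1 in 5 of 5 arms and furthest below it on 3L, at 0.406. Empty sequence beyond the last peak of an arm was not measured, so a longer stretch there would be missed. Among stretches before the first peak or between peaks, the 3 longest were 2R:1-936661 (937 kb), 2L:21409440-22044407 (635 kb) and 2R:1011008-1579468 (568 kb).

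Outside the 6 arms, 217 peaks fell on heterochromatic or unplaced sequence. The unplaced Uextra scaffolds held 146, the unplaced U scaffolds 35 and the heterochromatic scaffolds assigned to arms 36, of which 17 were on 3LHet and 10 on 2RHet. These peaks were narrower than those on the arms, with a median of 551 bp against 2024.5 bp, and their median score was 57.9 against 162 (permutation p = 1e-05 for width and 0.00031 for score). The median width was 553.5 bp on Uextra, 524 bp on U and 558 bp on the heterochromatic scaffolds. Scaffold lengths and mappability were not examined, so the differences need not reflect binding. The lower quartile of scores was higher off the arms (34.0 against 23.7). Among peaks above the median score, the ratio of median scores was 0.892 (permutation p = 0.331). A few peaks off the arms scored above 387, the upper quartile of the arm peaks. The highest in heterochromatic scaffolds was 2RHet:368589-374472, with a score of 773.58, followed by 3LHet:1281049-1288295 at 664.24 and 3RHet:1519808-1528006 at 660.67.

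Counted in bins of equal width on the log10 scale, the scores had 2 modes. Such bins widen with the score, so the modes and the dip between them depend on this scale. Weak and strong are therefore working labels and do not show 2 kinds of peak. One mode lay between scores of 10 and 12.6 (334 peaks) and the other between 398 and 501 (492 peaks), with a broad, shallow dip in between. The least filled bin of the dip, at scores of 39.8 to 50.1, held 126 peaks, and the bin at 25.1 to 31.6 held nearly as few (130 peaks). Below a score of 44.7, in the middle of the least filled bin, there were 1705 weak peaks (31.8%, Wilson 95% interval 30.6 to 33.1%), with a median width of 377 bp. The 3652 strong peaks had a median width of 2885 bp.

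**Figure D2:**
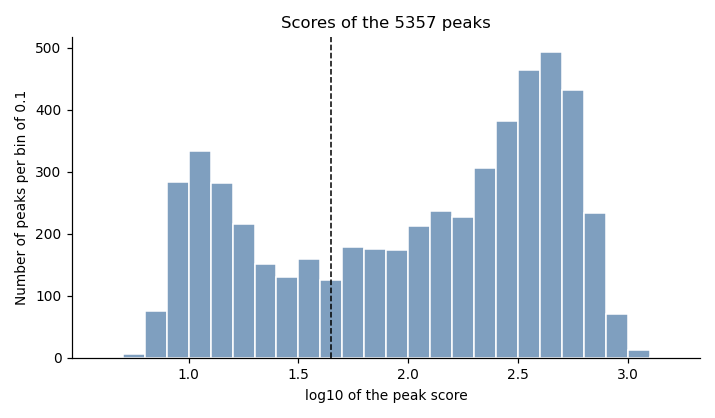
Histogram of the scores of the 5357 peaks, with the log10 of the score on the x axis and the number of peaks per bin of 0.1 on the y axis; the dashed line marks the score of 44.7 that separates weak from strong peaks. The bin at the upper mode holds 492 peaks, the bin at the lower mode 334 and the least filled bin between them 126. The dip is broad and shallow, and the bin at scores of 25.1 to 31.6 holds 130 peaks.

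Weak peaks lay next to strong ones more often than random placement gives. On the 6 arms, 972 of 1627 weak peaks (59.7%, Wilson 95% interval 57.3 to 62.1%) had an edge within 1 kb of a strong peak, against 6.29% ± 0.599 (SD over 10000 placements) when the weak peaks were placed at random outside the strong peaks. The ratio was 9.5 (permutation p = 0.0002 by random placement, the smallest these placements can give). It was 23.7 within 200 bp, 2.79 within 5 kb, and 1.88 when the weak and strong labels were permuted over the peaks of each arm in place of moving the weak peaks (permutation p = 0.0002 for each). With the limit between weak and strong at a score of 28.2, in the second least filled bin, 69.3% of 1374 weak peaks lay within 1 kb of a strong one, and with the limit at 100 the share was 43.6% of 2130 (ratios to random placement 10.4 and 8.1; permutation p = 0.0002 for both). Among 3513 strong peaks, 289 (8.23%) had another strong peak within 1 kb. Gaps under 200 bp separated 636 of the 5134 neighbouring pairs of peaks, and the smallest gap was 44 bp. The 915 strong peaks with a weak peak within 1 kb were wider than the 2598 without one, with medians of 3280 and 2832.5 bp (permutation p = 1e-05), and scored higher, with medians of 365 and 284 (permutation p = 1e-05). Among strong peaks of like score (20 classes), the geometric mean width was 1.05 times as large with a weak peak as without (permutation p = 0.00028). This comparison was chosen after the data were seen.

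Joining peaks with at most 1 kb between their edges left 4062 loci, of which 974 combined 2269 peaks and 3088 were single peaks. A strong peak was present in 3432 loci, and 630 consisted of weak peaks only. The 3 densest windows of 100 kb lay on 3R and 2R. The window 3R:15700001-15800000 held 20 peaks, 11 of them weak, in 8 loci. The window 3R:15300001-15400000 held 18 peaks, 9 of them weak, in 7 loci. The window 2R:13000001-13100000 held 16 peaks, 7 of them weak, in 8 loci. The median 100 kb window held 4 peaks, and 94 of 1177 windows held none.

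The last question was whether peaks were spread along the arms as independent points. They were not: 69.1% of the 5140 peaks on the arms had another peak centre within 10 kb, against 58.1% ± 0.77 (SD over 10000 placements) for centres placed uniformly, a ratio of 1.19 (two-sided permutation p = 0.0002 by random placement, the smallest these placements can give). Within 50 kb the ratio fell below 1: 98% of the peaks had another centre, against 98.6% for uniform placement (ratio 0.994, permutation p = 0.0004). A lower share at that distance means more isolated peaks than at random, which need not contradict clustering within 10 kb. Within 10 kb, with placements that kept the widths of the peaks, the expected share was 52% and the ratio 1.33 (permutation p = 0.0002). Joining peaks into loci left a smaller excess. Of the 3858 loci on the arms, 43.1% had another within 10 kb, against 35.2% ± 0.945 for the same loci placed at random with their widths, a ratio of 1.22 (permutation p = 0.0002). For the peaks above the median score, the ratio was 0.877 against points without width, since peaks of a median 3379 bp cannot lie as close as points, and 1.21 once the placements kept the widths (permutation p = 0.0002 for both).

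Neighbouring loci at distances of 5 to 10 kb numbered 748, against 589 ± 20.7 (SD over 1000 placements) at random. The number of loci fixes the total number of neighbouring pairs, so an excess in some distance classes goes with a deficit in others. The distance classes are therefore not separate findings, and uneven density along the arms was not told apart from spacing here. At 20 to 50 kb there were 1156 pairs, fewer than the 1439 ± 29.6 at random, and at 100 to 200 kb there were 150, more than the 103 ± 8.03 at random (permutation p = 0.002 for each, and 0.002 after Benjamini-Hochberg adjustment over the 6 distance classes; 0.002 is the smallest 1000 placements can give).

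**Figure D3:**
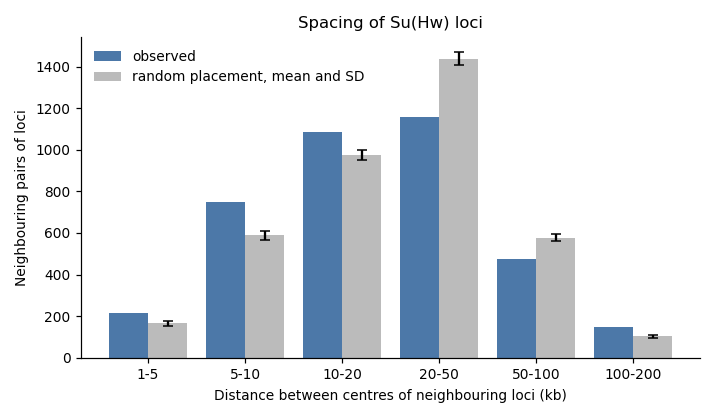
Number of neighbouring pairs of loci (y axis) by the distance between their centres in kb (x axis), as observed (blue) and as the mean over 1000 random placements of the same loci (grey, bars SD). Observed pairs exceed random placement at 5 to 10 kb (748 against 589) and fall below it at 20 to 50 kb (1156 against 1439). The total number of pairs is fixed by the number of loci, so the classes are not independent.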

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

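Alternatives that join peaks by their edges, keep widths in the placements, leave out the proximal ends, or concern the arm ends, the peaks off the arms and the weak peaks, were chosen after the data were seen; the others were planned. Of 63 alternative values, 57 kept their direction and their side of the threshold, or had no call to lose. Many of the 57 were of the latter kind: the large arms, the X comparison and the distal ends were never called, and list sizes had no test. Among results that were called, 3 alternatives turned in direction and 2 lost their call. The 57 of 63 therefore overstates how well the calls held. The list restricted to scores above the median holds 2673 peaks by construction. On chromosome 4, 1 Mb windows gave a ratio of 0.137 that no longer passed the test, because 1 complete window was left. The clustering ratio turned to 0.994 at 50 kb, a distance at which 98% of the peaks have a neighbour and 98.6% would have one at random. That change passed the test (permutation p = 0.0004). It means more isolated peaks than at random, which need not contradict clustering within 10 kb. The clustering ratio turned to 0.877 for the peaks above the median score, where points without width are the wrong comparison (1.21 with widths kept). For joined loci placed within 500 kb windows it was likewise 0.876 as points and 1.17 with widths kept. The ratio of median scores off and on the arms was 0.892 and lost its call among peaks above the median score (permutation p = 0.331). That is a selection on the score itself, which can draw the ratio towards 1. It also left few peaks off the arms, since 2639 of the 2673 lay on them. With edges joined the ratio was 0.232 and kept its call. With the widths of all peaks kept the clustering ratio was 1.33, and 1.22 after joining. The ratio of X to autosomes stayed between 0.978 and 1.06 over all alternatives and passed the test in none. No paired analysis was possible because the 1 peak list holds no values per library, and for the same reason no replicate could be left out. The alternatives fixed for gene annotation, gene lists and the motif were not run, since no genome of release 5 was used here. Depth limits are unknown: without read counts, a region without a peak cannot be told from one with too few reads to call.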

Other observations

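The tests of proximal scores, of peak width beside weak peaks and of clustering within 500 kb windows were chosen, in the form given, after results were seen; the tests of clustering of joined loci and of neighbouring scores were set out before theirs. The design holds no second condition, and no biological explanation was tested against another group.

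Beyond the regions above, a few peaks were far broader than the median of 1891 bp. The widest, chosen here after its value was seen, was 3L:22305528-22344863, which spans 39336 bp with a score of 890.52. The next were 2L:20176673-20198838 with 22166 bp and 3R:18162974-18178640 with 15667 bp. On the Uextra scaffolds the strongest peak, 1838931-1840217, scored 779.77.

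Weak peaks lie beside strong peaks. A candidate explanation is that the caller reported the edges of one enriched region as separate peaks. Strong peaks with a weak neighbour within 1 kb were wider than those without but also scored higher, and width follows score. Within classes of like score they were still 1.05 times as wide (permutation p = 0.00028, 915 against 2598 peaks). This small excess cannot decide the question. Splitting off an edge would also shorten the strong peak, and score differences can remain within a class. Separate weak binding sites next to strong ones stay open, as neither reads nor sequence were analysed here. If edges are the source, the number of distinct sites may be closer to the 4062 joined loci than to 5357.

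Peaks are clustered within 10 kb. Counting the edges of strong peaks as sites does not account for all of this, since joined loci were still 1.22 times as often within 10 kb of another as at random (permutation p = 0.0002). Differences in density between 500 kb windows do not account for all of it either: loci placed at random within their own window left a ratio of 1.17 (permutation p = 0.0002) when the placements kept the widths of the loci and the 1 kb between them. A first version that placed points without width gave 0.876 (permutation p = 0.0002); it was replaced because joined loci cannot lie as close as such points, so the outcome rests on that choice. Density differences on a scale below 500 kb, such as the spacing of genes, and uneven mappability stay open.

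Fewer peaks lie in the proximal 1 Mb of the arms. If enrichment over the input were weaker there, the remaining peaks could be expected to score lower. Their median score was 0.62 times that of the other peaks (101 for 70 peaks against 164 for 5061), a difference that did not pass the permutation test (p = 0.202). Weaker enrichment, reads lost in repeated sequence and a true scarcity of binding sites therefore cannot be told apart with 70 peaks and no sequence.

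A further hypothesis was that enrichment differs regionally, so that neighbouring loci have similar scores. Across 3845 adjacent pairs on the large arms, Spearman's rho was 0.0501 (permutation p = 0.0027 against 10000 permutations of the scores within arms, whose mean was 0.00264 ± 0.0161 SD). The relation is past the threshold and very small; pairs of loci are not independent replicates.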
